A study of Mus musculus with 2 samples.

How the data were processed

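Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found mostly at active promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the embryonic facial prominence of mouse embryos at embryonic day 14.5, per the labels. There was 1 group with 2 biological replicates, pools of 24 and 34 embryos of mixed sex. No condition was compared with another, so the replicates were compared with each other and genes were compared with genes within the tissue.

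Peak lists of 4 kinds were deposited on mouse build mm10 (GRCm38): the peaks of replicate 1, the peaks of replicate 2, peaks called on the reads of both replicates pooled, and the subset of the pooled peaks kept as replicated. Per the file headers and the deposited notes, each replicate's peaks came from its own alignment and a control alignment, the pooled peaks from both alignments and both controls, and the replicated list from the other lists. The rule for keeping a replicated peak, the aligner, the peak caller and their versions are not given in the sources used here. The fold enrichment (a ratio of ChIP to control signal) of each peak is the authors' deposited value. The −log10 q values are also the authors' deposited values, and so are the score used for display and the summit position, another deposited column. The score and the p-value column were not used here. Fold enrichment and −log10 q served to describe, rank or filter peaks within a list. Fold enrichment was also correlated across regions between the replicates and used to match genes within the replicated list. The lists hold no read counts, so sequencing depth is unknown, and every interval given covers the counting of peaks or genes only. A weak peak near the authors' threshold can be listed in 1 replicate and missed in the other for reasons of depth alone.

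Peaks on the 21 placed chromosomes were kept, which left out between 8 and 10 peaks per list. Gene positions came from GENCODE mouse release 21 on GRCm38, with 21938 protein-coding genes. Chromosome names and lengths of the reference were checked against those of the peak files. A promoter was any annotated transcription start site (TSS) of a protein-coding gene plus or minus 1000 bp. Every other peak was assigned to an exon, else an intron, else intergenic sequence. A promoter was called CpG-rich where the 500 bp on each side of the gene's 5′ end held at least 50% GC and an observed to expected CpG ratio of at least 0.6. A promoter peak can lie at another start of the gene, whose class was not measured. Distal peaks of a gene were replicated peaks with their midpoint within 100 kb of its 5′ end that overlapped no promoter. Coordinates are 1-based.

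Overlap between lists meant at least 1 bp, counted with bedtools 2.31.1. Chance overlap and chance positions came from 100 seeded shuffles of the peaks within their chromosomes, outside assembly gaps. In all, 19 gene lists were fixed before the data were examined, together with the tests and the other settings to try. Of 380 listed symbols 379 were found in the annotation, the exception being Ahsp, and the receptor list held the 1464 olfactory and vomeronasal receptor genes matched by name. Each list's share of genes with a promoter peak was compared with that of all other protein-coding genes by Fisher's exact test. Median promoter peak width and mean number of distal peaks were compared by permutation tests with 100000 random gene sets. All tests were two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Width and distal tests needed at least 5 members, which left 15 lists for width. Genes are not independent replicates, and neighbouring genes can share a peak, so the p-values describe this tissue and not a population of animals.

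The genes named were fixed by rule: for each list the 3 members with the highest fold enrichment at the promoter, and the members without a peak, or with one, where there were at most 4; the 10 genes with the widest and the 10 with the highest promoter peaks; the 5 strongest peaks away from promoters; and a set of facial and marker genes chosen in advance. The globin genes, Hnf4a, and the genes beside peaks of 1 replicate were named after their values were seen. Alternatives covered the peak threshold, the promoter window, the start sites used, the list used, the distance, the background genes and each replicate alone. Those added after seeing the data were 1 member per 100 kb neighbourhood, genes with no TSS of another gene within 2000 bp, distal peaks without those at long non-coding RNA starts, genes without a CpG-rich promoter, and Hox groups 5 to 13 among CpG-rich promoters in the pooled and replicate lists. A list of 30 hindbrain, spinal cord and trunk mesoderm regulators was fixed before its only test.

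The functions were tested on simulated data. Promoter calls matched a direct computation for 100% of 21938 genes. In 190 simulated lists of 20 genes, the share test called 96.3% of lists whose share was raised by 0.3, the width test called 85.3% of lists with 2-fold wider peaks, and the distal test called 82.6% of lists with 2-fold more peaks. None of the 3 tests called a simulated list without an effect. The simulated genes were drawn independently, so these rates do not cover lists of neighbouring genes that share peaks. Each effect was given to every list of a round, which weakens the adjustment. The rates thus do not apply where only some lists differ or where fewer than 20 members are tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.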

Results

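H3K9ac ChIP-seq peaks were mapped in the mouse embryonic facial prominence at embryonic day 14.5, when the palate is closing and the facial skeleton is forming. The tissue holds neural crest-derived mesenchyme, surface epithelium, muscle precursors, vessels, nerves and blood. The 2 biological replicates were pools of 24 and 34 embryos. On placed chromosomes replicate 1 had 68235 peaks and replicate 2 had 74613, with median widths of 284 and 249 bp. Peaks called on pooled reads numbered 76522, of which 36681 formed the replicated list used for genes. Depth was unknown because peak lists carry no read counts, and fold enrichments per peak are the authors' values.

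The 2 replicates shared the strong H3K9ac sites of the tissue and differed mainly in weak ones. Prrx1, a homeobox gene of limb and facial mesenchyme, had a promoter peak of 48.7-fold in replicate 1 and 40.1-fold in replicate 2. Actb, which encodes cytoplasmic actin, had 65.9-fold and 51.6-fold. Trp63, a master regulator of stratified epithelium, had a promoter peak in the list of replicate 2 and none in that of replicate 1, where a peak of 2.91-fold lay beside the promoter. Of all peaks, 50.1% of those of replicate 1 (34213 of 68235, 95% Wilson interval 49.8 to 50.5) and 49.2% of those of replicate 2 (36708 of 74613, interval 48.8 to 49.6) overlapped a peak of the other. Shuffled peaks overlapped in 3.40% and 3.11% of cases. The base-level Jaccard index was 0.507. Sharing rose with significance, from 20.6% and 19.9% of peaks with −log10 q below 2 to 98.6% and 98.9% at 10 to 20. From 20 upward 100% of the peaks of each replicate were shared. Across the 30032 replicated regions with a peak in both, Pearson's r of log2 fold enrichment was 0.90 and Spearman's rho was 0.865. These correlations are across regions, which are not independent replicates.

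**Figure D1:**
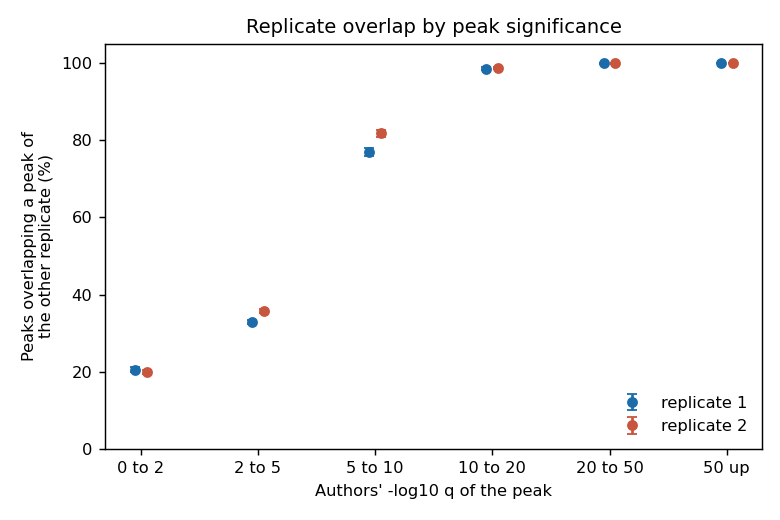
Percent of peaks of each replicate (y axis) that overlap a peak of the other by at least 1 bp, by the authors' −log10 q (x axis, classes), with 95% Wilson intervals. Sharing runs from 20.6% and 19.9% in the lowest class to 100% from 20 up.

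The replicated list kept the stronger and wider of the pooled peaks. It held 47.9% of them, with a median of 5.57-fold enrichment and 678 bp against 2.95-fold and 213 bp for those left out. Every replicated peak was identical to a pooled peak. Of the replicated peaks, 81.9% overlapped a peak of both replicates, 8.80% only one of replicate 1 and 8.50% only one of replicate 2, and 302 overlapped neither. Aif1, a macrophage gene, had a replicated promoter peak that overlapped a peak of replicate 1 (4.33-fold) and none of replicate 2, which had another peak at that promoter.

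H3K9ac in the facial prominence lay at promoters far more often than shuffled peaks did. Of the replicated peaks, 52.2% (19165) overlapped a promoter, against 5.79% of shuffled peaks (range 5.45 to 6.16 over 100 shuffles). Exons held 6.03% against 6.82%, introns 20.8% against 30.6%, and intergenic sequence 20.9% against 56.8%. Promoter peaks had a median width of 1250 bp and 14.4-fold enrichment, and the others 428 bp and 4.02-fold. In 1301 genes with 1 annotated start and an unshared peak, the summit lay downstream of the start in 86.7% (95% Wilson interval 84.7 to 88.4), at a median of 237 bp. The share at promoters was 35.9% and 36.3% in the lists of replicates 2 and 1, and 32.8% in the pooled list.

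Of the 5 strongest peaks away from protein-coding promoters, 3 lay at a long non-coding RNA start. The highest, at chromosome 7, 73555867 to 73558604 (mm10), lay at the start of 1810026B05Rik, 14037 bp from the 5′ end of Chd2, a chromatin remodeller gene. It reached 93.9-fold in the pooled call, 80.1-fold in replicate 1 and 75.5-fold in replicate 2. Malat1, an abundant nuclear RNA, lay at a peak of 7456 bp at chromosome 19, 5796149 to 5803604 (54.1-fold). A peak at chromosome 13, 48545952 to 48546587 (56.6-fold), lay at the start of 6720427I07Rik. The other 2 were inside the body of Tex2 at chromosome 11, 106500818 to 106502382 (60.8-fold), and in intergenic sequence at chromosome 10, 122982921 to 122987272 (53.1-fold), 89233 bp from Mon2. Of the 17516 replicated peaks away from promoters, 1224 (6.99%) lay at a long non-coding RNA start.

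The highest promoter enrichment in the tissue was at Srsf6, which encodes a splicing factor, with 89.1-fold at chromosome 2, 162930381 to 162933121 (74.9-fold in replicate 1, 69.1-fold in replicate 2). Next came Bicral, a chromatin remodelling subunit gene (83.0-fold), Rbm39, a splicing regulator (82.0-fold), Sfpq, an RNA-binding protein of paraspeckles (78.3-fold), Clk1, a splicing kinase (76.7-fold), and Tnpo1, a nuclear import receptor (76.4-fold). Actb had 74.9-fold. Hnrnpa2b1 and Cbx3 share a peak across their divergent starts (73.7-fold), and Tnrc18 had 73.4-fold. Of 21938 protein-coding genes, 14447 (65.9%, 95% Wilson interval 65.2 to 66.5) had a replicated promoter peak. The lists of the replicates gave 67.6% each, with 14371 genes in both, 463 in replicate 1 alone and 458 in replicate 2 alone. CpG-rich promoters had a peak in 97.7% of 9738 genes and the others in 40.4% of 12200.

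Transcription factors that pattern the facial mesenchyme all had promoter H3K9ac. The 50 listed members were marked in 50 of 50 cases, against 65.8% of other genes (Fisher's exact test, adjusted p = 1.03e-08), and each was also marked in both replicate lists. Among the 9738 genes with a CpG-rich promoter, of which 97.7% had a peak, the difference of 2.31 percentage points did not pass (exact adjusted p = 1), while among genes without one 13 of 13 members had a peak against 40.4% (exact adjusted p = 7.27e-05, a comparison chosen after seeing the data). This class was measured at the gene's 5′ end, and some of these 13 had their peak at another start. At Satb2 the 5′ end is at 56978650 of chromosome 1 and the peak at 56967639 to 56974588. The difference is therefore not shown for marked promoters that are themselves CpG-poor. Prrx1 was the strongest at chromosome 1, 163306094 to 163315653 (56.7-fold). Alx4, needed for the frontonasal skeleton, had 49.4-fold (35.2-fold and 45.7-fold in replicates 1 and 2), and Twist1, a cranial neural crest regulator mutated in craniosynostosis, had 48.3-fold (37.3-fold and 47.6-fold). The palate regulators Satb2 and Osr2 had 40.1-fold and 23.8-fold. Msx1 and Msx2, homeobox genes of tooth and skull, had 33.3-fold and 17.9-fold. The Dlx genes that set lower jaw identity, Dlx5 and Dlx6, had 32.01-fold and 22.4-fold on chromosome 6, and their relatives Dlx2 and Dlx1 had 17.5-fold and 12.7-fold. Tfap2a, a neural crest and ectoderm factor, had 30.6-fold, Pitx1 22.9-fold, Alx1 20.8-fold, Hand2 17.5-fold, Barx1 17.0-fold, Pitx2 12.5-fold and Pax9 12.3-fold. The weakest named member was Tbx22, an X-linked cleft palate gene, with 4.73-fold, and the lowest value among all 50 members was 3.64-fold.

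Signalling and epithelial genes of the face were marked at nearly every member. The signalling list had 39 of 40 members with a peak (exact adjusted p = 7.62e-06), led by the BMP receptor gene Bmpr1a (56.2-fold), the Wnt co-receptor gene Lrp6 (54.6-fold) and Smo, the Hedgehog signal transducer (51.2-fold). Bmp4 had 12.1-fold. The exception was Shh, the Hedgehog ligand of oral epithelium, with a promoter peak in the list of replicate 2 and none in replicate 1. Surface epithelium had 19 of 20 (exact adjusted p = 0.00906), led by Grhl2 (15.6-fold), Perp (14.7-fold) and Epcam (14.4-fold). Irf6, a clefting gene, had 6.14-fold and Trp63 had 4.41-fold, and Grhl3 lacked a replicated peak but had one in the list of replicate 2 and in the pooled list. The housekeeping list had 20 of 20 (exact adjusted p = 0.00125), led by Actb (74.9-fold), Eef1a1 (69.7-fold) and Ywhaz (66.5-fold). Among genes with CpG-rich promoters only, signalling, epithelium and housekeeping did not pass, and among genes without one signalling and epithelium did (exact adjusted p = 0.00225 and 0.00384) and the 4 such housekeeping genes did not (0.0634). As above, the class was measured at the 5′ end, away from the peak in some members. The epithelial call was lost in the list of replicate 1 (exact adjusted p = 0.0501).

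Skeletal, vascular and neural lists did not pass the threshold for a difference in promoter share by Fisher's exact test with adjustment. Cartilage had 16 of 18 (exact adjusted p = 0.0783), led by Sox6 (27.9-fold), Sox9, the chondrocyte master regulator (25.9-fold), and Col9a2 (12.5-fold). A wider but weaker promoter peak of Sox6 (5.98-fold) is shared with 1110004F10Rik. Col2a1, which encodes the main cartilage collagen, had 12.4-fold, and Col10a1 and Snorc had no replicated peak, Snorc having one in the list of replicate 1 alone. Bone had 8 of 14 (exact adjusted p = 0.682), with Runx2 at 32.8-fold, Col1a1 at 30.1-fold and Mef2c at 22.9-fold. Skeletal muscle had 16 of 22 (exact adjusted p = 0.731). Its strongest, Mylpf at 38.3-fold, shares its peak with Tbc1d10b, and Tbx1 had 17.5-fold (5.07-fold in replicate 1, 19.7-fold in replicate 2), Pax7 12.3-fold and Myod1 7.07-fold. Endothelium had 15 of 20 (exact adjusted p = 0.613), with Fli1 at 34.3-fold, Egfl7 at 18.3-fold under a peak shared with Gm20532 and Erg at 15.3-fold. Neurons had 15 of 19 (exact adjusted p = 0.487), with Elavl4 at 19.9-fold, Isl1 at 11.8-fold and Gap43 at 10.03-fold. Dcx, Neurod1, Phox2b and Snap25 lacked a replicated peak, though Dcx and Snap25 had one in the list of replicate 1 and in the pooled list. Schwann cells and melanocytes had 11 of 16 (exact adjusted p = 1), with Mpz at 31.1-fold under a peak shared with Sdhc, Pmel at 17.9-fold under a peak shared with Cdk2, Mitf at 15.8-fold and Sox10 at 5.09-fold. Forebrain and eye had 11 of 16 (exact adjusted p = 1), with Bcl11b at 42.7-fold, Emx2 at 20.8-fold, Otx1 at 10.4-fold and Foxg1 at 7.80-fold. Heart muscle had 9 of 16 (exact adjusted p = 0.591), with Myl4 at 60.7-fold under a peak shared with Cdc27, Hcn4 at 14.4-fold and Ryr2 at 13.5-fold. Cartilage passed the threshold in the list of replicate 1 (adjusted p = 0.0211), and so did endothelium (exact adjusted p = 0.0148), whereas skeletal muscle passed in the list of replicate 2 (adjusted p = 0.0392) but differed by -10.03 percentage points from other genes among peaks with −log10 q of at least 5 (0.473). With 5′ ends only, cartilage passed as higher (exact adjusted p = 0.0406) and heart muscle as lower (0.0301), and cartilage also passed among genes with no other TSS within 2000 bp, a setting chosen after seeing the data (0.0458), and among those without a CpG-rich promoter, likewise chosen (0.00716).

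Genes of blood, liver, germ line, the posterior body axis and chemosensory neurons were marked less often than all other genes, but the blood lists did not pass against genes of the same promoter class. None of the erythroid or macrophage members had a CpG-rich promoter, and among genes without one, a comparison chosen after seeing the data, neither list passed (exact adjusted p = 0.612 and 0.775, against 40.4% of other genes). In that comparison liver, with 1 of 18, and germ line, with 0 of 13, passed as lower (exact adjusted p = 0.00448 each), Hox groups 5 to 13, with 3 of 10, did not (0.855), and 2 of 1463 receptor genes had a peak against 45.9% of other genes. Among CpG-rich promoters Hox groups 5 to 13 and germ line passed as lower (exact adjusted p = 1.33e-17 and 1.06e-06), the Hox difference being -74.3 percentage points here and -39.6 in the pooled list, and the single liver and the single receptor gene of that class had a peak. Those Hox members lie in 4 clusters and are not independent, and their comparison was not repeated with 1 member per neighbourhood. Erythroid genes had 4 of 14 (exact adjusted p = 0.0148): Klf1 at 19.2-fold, Nfe2 at 12.95-fold, Epor at 7.57-fold and Gypa at 6.86-fold. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had none, though their near-identical copies leave read placement uncertain. Macrophage and leukocyte genes had 5 of 16 (exact adjusted p = 0.0131), led by Coro1a (9.03-fold), Spi1 (5.91-fold) and Aif1 (4.26-fold). Hox paralogue groups 5 to 13, which pattern the trunk and limbs, had 7 of 27 (exact adjusted p = 0.000123), led by Hoxd8 (7.999-fold), Hoxa7 (6.90-fold) and Hoxc6 (6.10-fold). Groups 1 to 4, active in the hindbrain and neck, had 10 of 12 (exact adjusted p = 0.381), led by Hoxa2 (11.01-fold), Hoxb2 (9.93-fold) and Hoxa1 (9.31-fold), with Hoxb1 and Hoxc4 lacking a replicated peak. Hoxb1 nevertheless had a promoter peak in the lists of both replicates and in the pooled list, and Hoxc4 in those of replicate 1 and the pooled reads. Liver genes had 2 of 19 (exact adjusted p = 4.31e-06): Foxa3 under a peak shared with Sympk and Apoh under one shared with Prkca, while Alb and Hnf4a had none. Germ line genes had 2 of 20 (exact adjusted p = 2.17e-06), Dazl, and Gdf9 under a peak shared with Uqcrq. Receptor genes had 3 of 1464 (0.205%), namely Olfr94, Olfr156 and, under a peak shared with Nt5c3, Vmn1r4, with a p-value below the smallest the software could represent. The calls for macrophage genes and for Hox groups 5 to 13 were lost in the pooled list (exact adjusted p = 0.153 and 0.111), and the former in replicate 2 alone (0.502) and the latter in replicate 1 alone (0.0566). With 1 member per 100 kb neighbourhood, a setting chosen after seeing the data, Hox groups 5 to 13, macrophage and erythroid genes missed the threshold (exact adjusted p = 0.0850, 0.0556 and 0.0600) with fewer members and differences of -45.9, -30.2 and -32.5 points against -39.98, -34.6 and -37.3, while Hox groups 1 to 4 passed as higher in the list of replicate 1 (0.0211) and in the pooled list (0.0497).

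**Figure D2:**
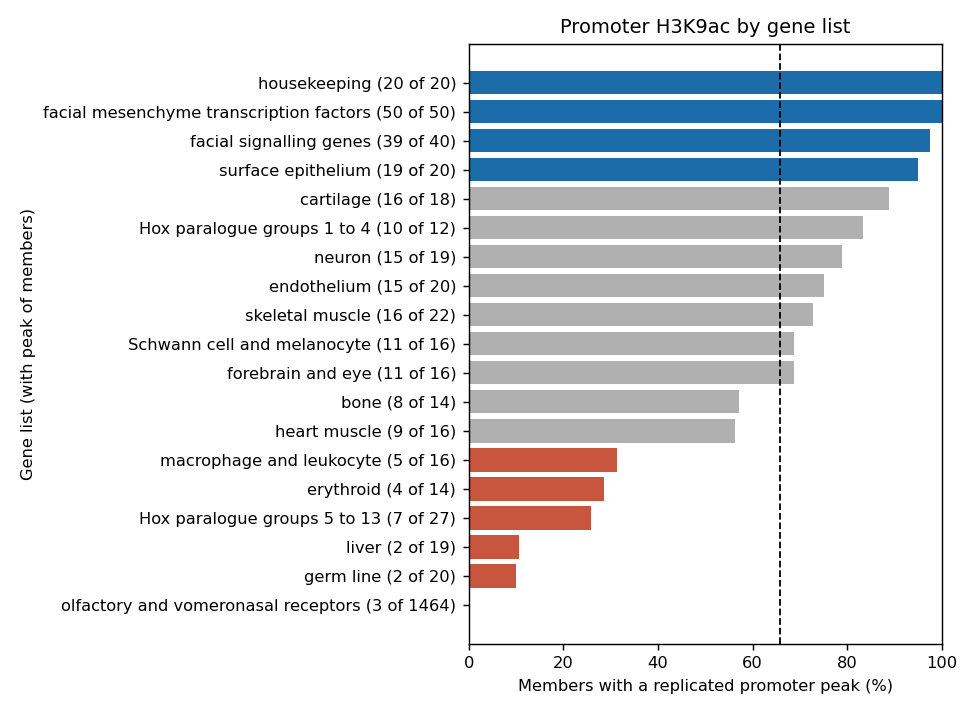
Percent of each gene list's members with a replicated promoter peak (x axis) for the 19 lists, with counts in the labels; the dashed line is all protein-coding genes (65.9%). Blue bars lie above and red bars below other genes by Fisher's exact test after adjustment, and grey bars did not pass it.

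Promoter peaks were widest at facial transcription factors. Tbx2, a T-box transcription factor, had the widest promoter peak of any protein-coding gene, 15996 bp at chromosome 11, 85829175 to 85845170. It was followed by the Wnt ligand gene Wnt5a (14970 bp), Six2 (14784 bp), Tnrc18 (13891 bp), Meis2 (13794 bp), Tbx3 (12293 bp), Setd1b, a histone methyltransferase gene (11225 bp), Lhx8 (10096 bp), Nfib (9914 bp, at an internal start) and Mn1 (9703 bp). Of the 500 widest genes 35 were facial transcription factors, where list size gave 1.73. Their median was 5145.5 bp against 1643 bp for other genes (permutation test, adjusted p = 0.0001, from the smallest p the permutations can give). Signalling genes had a median of 3263 bp (adjusted p = 0.0001, likewise), bone genes 3184.5 bp over 8 members (permutation, adjusted p = 0.0015) and housekeeping genes 2356.5 bp (adjusted p = 0.0102). Narrower were skeletal muscle at 801.5 bp (adjusted p = 0.00015), heart muscle at 791 bp over 9 members (permutation, adjusted p = 0.0057), Hox groups 1 to 4 at 960.0 bp (adjusted p = 0.0151), Hox groups 5 to 13 at 475 bp over 7 members (permutation, adjusted p = 0.0003) and macrophage genes at 338 bp over 5 members (permutation, adjusted p = 0.0001). Median fold enrichment of these narrower lists was also low, from 4.26 to 6.42, against 21.5 for all protein-coding genes with a peak. Surface epithelium, endothelium and neurons, at 6.86, 6.15 and 5.95, did not pass as narrower in the replicated list. Only facial transcription factors were compared at matched fold enrichment, so width was not separated from strength in the other lists. No difference passed for surface epithelium at 1498 bp (permutation adjusted p = 0.533), cartilage at 1935.5 bp (0.337), endothelium at 1424 bp (0.425), Schwann cells and melanocytes at 1481 bp (0.57), forebrain and eye at 2242 bp (0.104) or neurons at 1145 bp (0.0514). Among CpG-rich promoters the skeletal muscle difference turned to 469 bp wider and did not pass (permutation adjusted p = 0.348), and the housekeeping difference was lost (0.0929), as was that of heart muscle with −log10 q of at least 5 (0.121) and that of Hox groups 1 to 4 when peaks within 1000 bp were merged (0.66) or genes with another TSS within 2000 bp were left out (0.0789). Bone, heart muscle, macrophage genes and Hox groups 5 to 13 had too few members among CpG-rich promoters to be tested. In the replicates' own lists neurons passed in both (permutation adjusted p = 0.00726 and 0.00266), endothelium passed as narrower in replicate 1 (0.00351), and cartilage and forebrain medians lay below those of other genes, the latter past the threshold in replicate 2 (0.0163), whereas forebrain genes passed as wider when peaks were merged (0.0328) or genes with another TSS within 2000 bp were left out (0.0474).

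**Figure D3:**
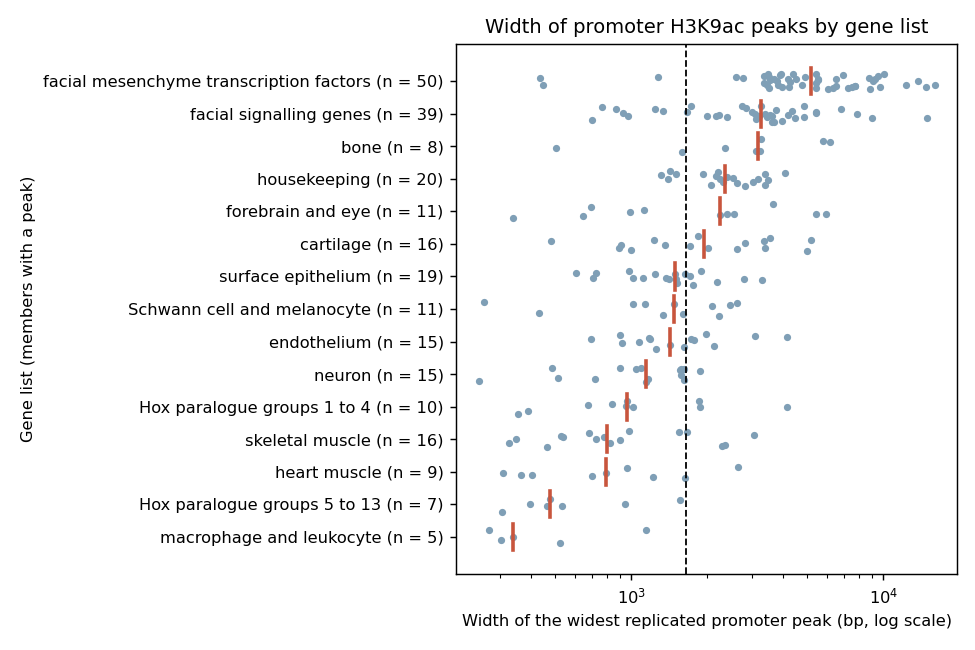
Width of the widest replicated promoter peak (x axis, bp, log scale) of each member with a peak, for the 15 lists with at least 5 such members; red bars are list medians and the dashed line the median of other genes. Facial transcription factors have a median of 5145.5 bp and macrophage genes 338 bp.

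Facial transcription factor genes also had more H3K9ac peaks around them. They averaged 8 distal replicated peaks within 100 kb against 2.82 for other genes (permutation test, adjusted p = 0.00019, from the smallest p the permutations can give), with 19 at Mn1, 12 at Hand2, 11 at Alx4 and 9 each at Dlx5 and Dlx6, which share a neighbourhood. Any peak outside the promoter windows counts as distal here, so pieces of a wide acetylated stretch beside a promoter can count. The number is thus not separate from peak width. Higher means were also found for Hox groups 1 to 4 (8.33, permutation adjusted p = 0.00114), housekeeping (7.10, adjusted p = 0.000633), skeletal muscle (6.23, adjusted p = 0.0026), bone (6.21, adjusted p = 0.0217), Hox groups 5 to 13 (5.96, adjusted p = 0.00205) and macrophage genes (5.63, adjusted p = 0.0366). Col1a1 had 18 and Actb 17. Receptor genes averaged 0.244 (permutation adjusted p = 0.00019). The means of signalling (3.90), surface epithelium (4.55), cartilage (3.33), endothelium (3.15), erythroid (3.21), neuron (2.21), Schwann cell and melanocyte (3.81), forebrain and eye (3.81), heart muscle (4.50), liver (1.89) and germ line genes (2.5) did not pass, with permutation adjusted p from 0.152 to 0.781. In the list of replicate 2, the differences from other genes were 1.06 peaks for Hox groups 1 to 4 and -0.395 for groups 5 to 13 (permutation adjusted p = 0.754 and 0.894), and macrophage genes missed the threshold in the list of replicate 1 (0.0845). Macrophage genes also missed it with −log10 q of at least 5, with fold of at least 4 and within 50 kb, with differences of 1.33, 1.28 and 1.05 against 2.8 (permutation adjusted p = 0.129, 0.113 and 0.184), and bone and Hox groups 1 to 4 missed it within 200 kb (0.0705 and 0.114). There the bone difference was larger than within 100 kb and that of Hox groups 1 to 4 was smaller. In the pooled list both Hox lists missed it (permutation adjusted p = 0.110 for groups 1 to 4 and 0.234 for groups 5 to 13), with differences close to those in the replicated list, and signalling passed (0.0333). With 1 member per 100 kb neighbourhood, a setting chosen after seeing the data, macrophage genes and Hox groups 5 to 13 missed it (permutation adjusted p = 0.0698 and 0.399), with fewer members and somewhat smaller differences. Hox groups 1 to 4 were left with fewer than 5 members in that setting and were not tested. Among genes with a promoter peak, bone, muscle, macrophage and Hox groups 5 to 13 missed it (permutation adjusted p = 0.0559, 0.230, 0.154 and 0.446) with fewer members and differences of 4.42, 1.92, 4.42 and 2.13 peaks against 3.39, 3.40, 2.8 and 3.14, and without peaks at long non-coding RNA starts, as chosen after seeing the data, so did both Hox lists (0.148 and 0.375).

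**Figure D4:**
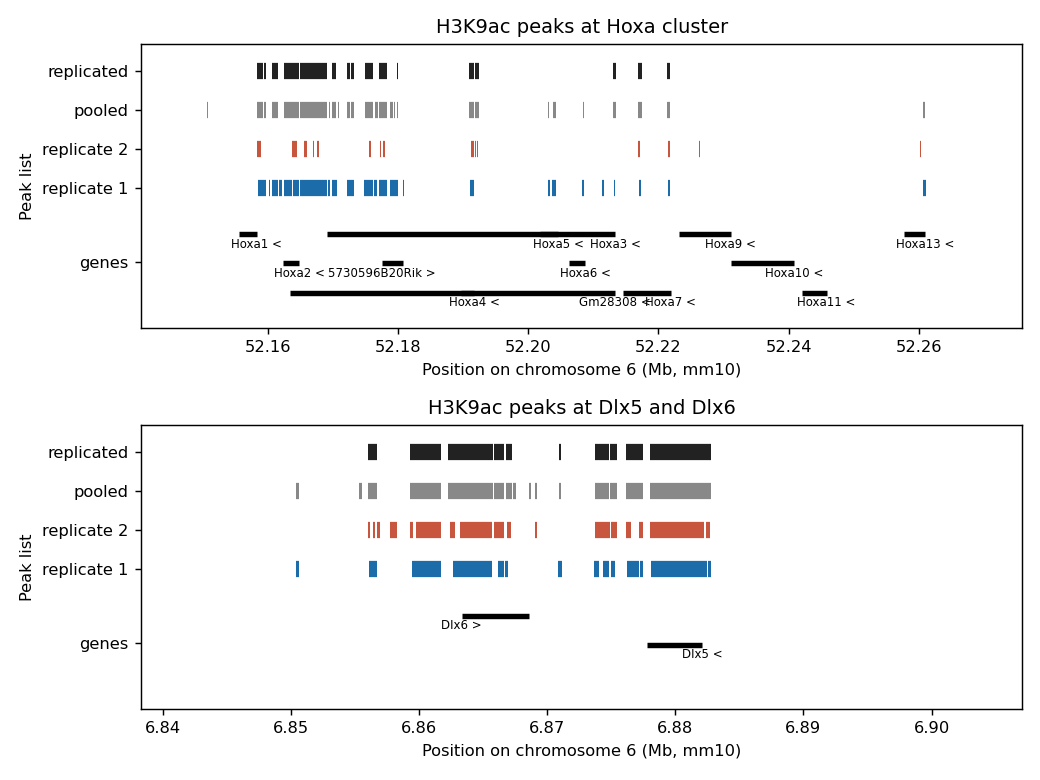
Peaks of the 4 lists (rows) and protein-coding genes (black bars, arrow showing strand) at the Hoxa cluster and at Dlx5 and Dlx6 on chromosome 6 (x axis, Mb, mm10). Across the Hoxa cluster, replicate 1 has 26 peaks and replicate 2 has 16.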

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

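The alternatives of 1 member per 100 kb neighbourhood, genes with no other TSS within 2000 bp, genes without a CpG-rich promoter, and distal peaks without those at long non-coding RNA starts were chosen after seeing the data. Facial transcription factors kept their wider peaks and more distal peaks past the threshold under each alternative run, with differences of 2594.5 to 7473.5 bp and 3.78 to 9.36 peaks. Width was not rerun with fold of at least 4, with 5′ ends only or among genes without a CpG-rich promoter. Values below are the percent of members with a promoter peak, the median width in bp or the mean number of distal peaks, each as list minus other genes. The cause of the changes was not tested, except that among CpG-rich promoters nearly every gene had a peak.

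Overlap between replicates was 40.1% and 41.7% at 50% of the peak's length, 34.3% and 31.3% at reciprocal 50%, 81.6% and 86.4% with −log10 q of at least 5, and 72.9% and 73.8% with fold enrichment of at least 4. The replicated share of pooled peaks was 94.8% and 96.3% under the last 2 settings. Peaks at promoters made up 62.7% and 65.3% under those settings, 48.6% and 58.9% with windows of 500 and 2000 bp, 41.1% with 5′ ends only, 32.8% in the pooled list, and 35.9% to 36.3% without 1 replicate. Genes with a promoter peak made up 64.6%, 64.1%, 65.3%, 66.7%, 62.1% and 68.7% in the same order, and 67.6% without either replicate.

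Promoter share among CpG-rich promoters was no longer past the threshold for facial transcription factors (2.31), signalling (2.31), epithelium (2.30) and housekeeping (2.30). The sign turned for bone, liver and receptors (2.30 each), endothelium (-12.0), neuron (-6.04) and forebrain (-8.82), none of them past it. Among genes without one, erythroid (-11.9), macrophage (-9.20), Hox 5 to 13 (-10.4) and housekeeping (59.6) were lost, cartilage (44.2) passed, and bone (13.4) and heart (5.02) turned. With −log10 q of at least 5 the sign turned for muscle (-10.0) and Schwann cells (-2.07), and with fold of at least 4 for muscle (-9.59), Schwann cells (-1.62) and forebrain (-1.62). With 5′ ends only it turned for endothelium (-2.14), while cartilage (26.8) and heart (-30.9) passed. In the pooled list macrophage (-18.7) and Hox 5 to 13 (-16.9) were lost, Hox 1 to 4 (31.3) passed and heart turned (0.0656). With 1 member per neighbourhood erythroid (-32.5), macrophage (-30.2) and Hox 5 to 13 (-45.9) were lost. With no other TSS nearby macrophage (-25.3) was lost and cartilage (27.2) passed. Without 1 replicate the ranges were 22.4 to 32.4 for epithelium, 21.3 to 26.8 for cartilage, 18.8 to 23.3 for muscle, -10.5 to -3.31 for bone (-8.72 in the replicated list), 6.09 to 21.9 for neurons (13.1 there), 13.6 to 13.7 for forebrain (2.90 there), 12.4 to 27.4 for endothelium, -42.6 to -11.4 for macrophage, -11.4 to 1.13 for Schwann cells, 7.41 to 32.4 for Hox 1 to 4, -34.3 to -19.5 for Hox 5 to 13 and -17.6 to 1.13 for heart. Lists above other genes numbered 0 among CpG-rich promoters, and lists below numbered 2 there, 3 among genes without one and 3 with 1 member per neighbourhood.

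Width for neurons passed the threshold with −log10 q of at least 5 (-521), in the pooled list (-512), among CpG-rich promoters (-674) and with 1 member per neighbourhood (-528.5). Forebrain passed with merged peaks (1113) and with no other TSS nearby (755.5), and turned in the pooled list (-480.0). Hox 1 to 4 was lost with merged peaks (-191) and with no other TSS nearby (-614), heart with −log10 q of at least 5 (-575), and housekeeping among CpG-rich promoters (539.5). Muscle turned there (469), and Schwann cells turned with merged peaks (89.5). Without 1 replicate the ranges were -403 to -102 for cartilage, -618 to -372 for endothelium, -671 to -585 for neurons and -550.0 to -472 for forebrain. Wider lists numbered 2 among CpG-rich promoters. Narrower lists numbered 2 there, 3 with −log10 q of at least 5, and 7 to 8 without 1 replicate. Among CpG-rich promoters bone, macrophage, heart and Hox 5 to 13 had fewer than 5 members with a peak and were not tested. A list below that number in any setting was not tested, which also lowers these counts.

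Distal peaks for signalling passed in the pooled list (3.96). Bone was lost within 200 kb (4.57) and among genes with a promoter peak (4.42), where muscle (1.92), macrophage (4.42) and Hox 5 to 13 (2.13) were lost too. Macrophage was also lost with −log10 q of at least 5 (1.33), fold of at least 4 (1.28), within 50 kb (1.05) and with 1 member per neighbourhood (2.75). Hox 1 to 4 was lost in the pooled list (5.96), within 200 kb (4.34) and without long non-coding RNA starts (2.27). Hox 5 to 13 was lost in the pooled list (2.99), with 1 member per neighbourhood (2.58) and without long non-coding RNA starts (0.867). Erythroid turned within 50 kb (-0.375) and germ line in the pooled list (0.404). Without 1 replicate the ranges were 4.25 to 6.59 for macrophage, 1.06 to 10.2 for Hox 1 to 4 and -0.395 to 6.02 for Hox 5 to 13. Lists above other genes numbered 3 among genes with a promoter peak and 4 with 1 member per neighbourhood, and lists below numbered 0 among genes with a promoter peak. That 0 is not a lost result, since the receptor list had only 3 members with a promoter peak and was not tested there. With 1 member per neighbourhood Hox 1 to 4 had fewer than 5 members and was not tested. No paired analysis was possible because there was 1 group. Unknown depth limits any reading of peaks near the authors' threshold.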

Other observations

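Chosen only after the result was seen were the tests of CpG-rich sequence, of CpG-rich peaks of 1 replicate, of whole-genome sensitivity and of Hox promoters that are not CpG-rich, as were the patterns they address and the repeat of the Hox comparison in the other peak lists. The comparison of Hox genes among CpG-rich promoters was a setting chosen in advance, and it was taken as a test of this pattern only after its value was known. Written in advance were the tests on peak strength, joined peaks, posterior regulators and mapping. The test of posterior regulators was changed from their promoter calls to peaks within 100 kb of them before it was run, leaving out those within 100 kb of a Hox cluster.

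Peaks of 1 replicate had neighbours of their own. Among the 10 most significant peaks listed in replicate 1 alone were peaks near Hoxa1 (−log10 q of 19.6, chromosome 6, 52160657 to 52161519), Bdnf, a neurotrophin gene (18.8), Per1, a clock gene (17.0), and Zic4, a zinc finger gene of the dorsal neural tube (15.2). The 10 of replicate 2 alone included peaks near Sptlc2 (19.3), Prkacb (16.2) and, at 2 sites, the frontonasal gene Alx1 (15.05 and 13.9). A peak listed in 1 replicate can still overlap a peak of the replicated list, as that near Hoxa1 does (52160595 to 52161519). Macrophage genes had 0 promoters called in replicate 1 alone and 5 in replicate 2 alone (Fisher's exact test, p = 0.0301, adjusted p = 0.511), which did not pass. Chromosome X held 5.12 and 5.54 shared peaks per Mb against 13.5 and 14.5 on autosomes in replicates 1 and 2, and 1.81 and 1.34 unshared peaks against 13.7 and 15.3.

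Facial transcription factors had a median promoter peak width of 5145.5 bp. Of 10000 gene sets matched on the length of CpG-rich sequence within 5 kb, the central 95% had medians of 1827 to 2678 bp, and of sets matched on fold enrichment 1551 to 2032 bp. Members whose peak covered no other coding promoter (49) had a median of 5385 bp against 1305 to 1852 bp for random sets. These values argue against CpG-rich sequence within 5 kb of the 5′ end, peak strength and joining across other coding promoters as the whole cause. Some peaks reached beyond that window, as at Satb2 (5′ end at 56978650 of chromosome 1, peak at 56967639 to 56974588). CpG-rich sequence along the whole peak therefore stays open. Joining across long non-coding RNA starts or a gene's own other starts was not tested. A broad acetylated domain at these regulators is a hypothesis, and no biological explanation could be tested with 1 tissue.

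Peaks listed in 1 replicate within the 4 Hox clusters were in replicate 1 in 70 of 88 cases (79.5%, 95% exact binomial interval 69.6 to 87.4), with more in replicate 1 in each cluster, from 35 against 5 at Hoxb to 6 against 3 at Hoxc; for promoters of the 39 Hox genes, 10 were called in replicate 1 alone and 3 in replicate 2 alone, which did not pass (Fisher's exact test, p = 0.0901). Some of these Hox peaks, such as that near Hoxa1, overlap a peak of the replicated list. Over the whole genome the share in replicate 1 was 47.3%, which argues against a generally more sensitive list. Among CpG-rich peaks it was 50.03% outside the clusters and 72.4% within (interval 52.8 to 87.3), which narrowly argues against a CpG preference, and peaks of a cluster are not independent. Near 30 posterior regulators it was 43.9% (interval 38.5 to 49.4), which includes the genome share and gives no sign of an excess, so more hindbrain, neck or trunk tissue in replicate 1 may or may not contribute. Dissection differences between the pools stay open.

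Promoters of Hox groups 5 to 13 mostly lacked a replicated peak (a difference of -39.98 percentage points from other genes), but the difference was -16.9 in the pooled list and -19.5 in that of replicate 1, neither past the threshold, so the pattern holds for the replicated list and not for every list. Among CpG-rich promoters 4 of 17 had one against 97.8% of other genes, a difference of -74.3 percentage points (Fisher's exact test, adjusted p = 1.33e-17). The difference shrank to -56.7 in the list of replicate 2, -39.4 in that of replicate 1 and -39.6 in the pooled list. It passed in each by the same exact test (adjusted p = 5.88e-12, 2e-07 and 1.01e-07). These 17 members lie in 4 clusters, and the p-values treat them as independent genes, which they are not. The comparison was not repeated with 1 member per neighbourhood. These members were chosen as CpG-rich, so a CpG-poor promoter could not be their cause by definition. Their low share argues only against CpG-poor promoters as the whole cause of the list's pattern. Of the 10 others 3 had a peak, a difference of -10.4 points from genes of that class (adjusted p = 0.855 by the same exact test), so for them the promoter class stays open. The median share of 31-base words in their promoters that occur once in the genome was 100% (lowest 89.6%), which argues against reads lost between paralogues. Silencing of posterior Hox genes in the face is a hypothesis that these data could not test, since no repressive mark was analysed here.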
